A study of Homo sapiens with 6 samples.

How the data were processed

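Gene expression was measured on 6 arrays of HT29, an established human colorectal adenocarcinoma cell line. Per the labels, 3 arrays came from cells with a control construct and 3 from cells with a laminin α1 expression construct. The series' design text states 3 independent culture passages per group, and the labels give 7 days of growth. Total RNA was extracted with Tri Reagent and made into cRNA by the Affymetrix protocol, per the labels' protocols. The labels also name the dye Cy3, which that protocol does not commonly use, and the table holds 1 value per probe set and array, which was treated as a single channel. Scan dates, the sequence carried by the construct and the number of cell clones behind each group are not given in the sources used here.

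The deposited values are log2 expression values per probe set. They were made with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarises the probes of a probe set, so the arrays share nearly one distribution and a change of all genes together could not be seen. The authors' values were used as deposited, with no further normalization. The table held 33297 probe sets. Values ranged from 2.40 to 13.9, and the medians of the arrays lay between 6.45 and 6.49. For arrays, the number of arrays, 3 per group, limits the precision, and the median standard error of a log2 difference was 0.0754. The arrays of a group are culture passages, so standard errors and p values measure the spread between passages. Since the number of clones is not given, they cannot be read as the spread between independently made cell populations.

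Probe sets were named from the platform annotation, which listed exactly 1 gene symbol for 19460 probe sets, several for 1754 and no entry for 12083. Only probe sets with 1 symbol were used as genes, 18417 in all, and the brightest was taken for the 769 genes with more than 1. Genes with a mean level over all 6 arrays above the 25th percentile, log2 5.50, were tested, which left 13812.

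Differences are laminin α1 minus control, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and intervals are 95% intervals of that fit. All adjusted p values of genes are from limma. Exact permutation tests of 3 against 3 arrays are two-sided and cannot give a p below 0.1.

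The lists covered laminin chains, other basement membrane and matrix genes, integrins and laminin receptors, focal adhesion and actin, angiogenic factors, chemokines and receptors, Wnt target genes, enterocyte differentiation, secretory lineage, epithelial junctions and keratins, mesenchymal transition, proteases and inhibitors, and cell cycle. They further covered p53 target genes, hypoxia and glycolysis, unfolded protein response, interferon response, NF-kB and inflammatory genes, growth factor signalling and immediate early genes, cholesterol and lipid synthesis, NRF2 and xenobiotic metabolism, colon stem cell and progenitor markers, fibroblast markers, endothelial and blood cell markers, and housekeeping genes. These 25 lists were fixed before the data were examined and hold 670 genes, of which 617 were on the array and 505 were tested. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list, and limma's fry, which asks whether the genes of a list move on balance one way, were run as alternatives. Counts of members are given over all genes tested and adjusted over the list alone.

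The genes named were set by a rule fixed before the data were examined. It took LAMA1, VEGFA, CXCR4, ITGA2 and ITGB1 whatever their values. It added the 8 largest higher and 8 largest lower differences among genes past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p.

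The other alternatives were no filter, a filter at the 50th percentile, the mean of a gene's probe sets, all probe sets tested separately, centring on array medians, repeated quantile normalization, a trended and robust eBayes, array weights, the replicate number as a block, and each array left out in turn. An adjusted p under 0.01, a fold of at least 2, and laminin chains without LAMA1 were also tried. Runs of neighbouring genes were sought after the data had been examined, with a running median over 25 genes compared with 1000 shuffled gene orders. Gene order came from the RefSeq annotation of the assembly GRCh38.p14, which was used for order only. Where 1 group's mean lay below the level filter, a lower bound of the fold with the filter level as the floor was added after the data had been examined. No background measure is given in the sources used here.

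The fit was tested on simulated data for 13812 genes of this comparison. It recovered 98% of 100 genes changed by log2 0.5 and 100% of 100 changed by log2 1, with 14 false calls among 212 and 0 wrong signs. Of 25 simulated lists it called 1, the list that had been shifted. The search for runs found 60 of 60 genes of a single simulated run and 8 others. The simulated genes were drawn independently of one another. The simulations therefore do not test how list calls or runs behave where genes are correlated.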

Results

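The data are log2 expression values from 6 arrays of HT29 colorectal cancer cells, 3 with a control construct and 3 with a construct for laminin α1, a chain of the basement membrane protein laminin. The question, from the title of the series, is what the laminin α1 chain changes in these cells in culture. LAMA1 itself, which encodes the chain, had values of 5.71, 5.63 and 5.60 in the control arrays and 5.79, 5.72 and 5.71 in the laminin α1 arrays. The difference was 0.09 (95% interval -0.05 to 0.24, n = 3 per group) and did not pass the limma test (adjusted p = 0.535). It had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The level of LAMA1 lay at the 27.8th percentile of all genes, and the sources used here do not say whether its probes match the construct, so LAMA1 does not verify the labels. The groups below are therefore arrays labelled laminin α1 and arrays labelled control.

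In the arrays labelled laminin α1, 12 of 25 tested genes of the intestinal secretory lineage fell and 22 of 34 tested genes of the interferon response rose, with 0 past the threshold the other way in either list. Both lists were called by camera at its preset correlation and neither with an estimated correlation (adjusted p = 0.173 for the secretory and adjusted p = 0.185 for the interferon list with an estimated correlation). MUC2, the gel-forming mucin of goblet cells, was 4.60-fold lower, and ATOH1, the transcription factor that directs cells to the secretory lineage, was 5.40-fold lower. IFITM1, a membrane protein induced by interferon, rose 2.36-fold. LGR5, a receptor that marks intestinal stem cells, rose 2.60-fold. Of 15 tested stem cell and progenitor markers only LGR5 rose past the threshold and 1 fell. Camera did not call that list (adjusted p = 0.193). ITGA2, a collagen and laminin receptor subunit, rose 1.85-fold. ITGA2 and ATOH1 each lay in a run of neighbouring genes that shifted together.

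Of 13812 genes tested, 730 passed the threshold, 372 higher and 358 lower. Among these, 67 differed by at least 2-fold, 28 higher and 39 lower. The 3 arrays of one group lay wholly on one side of the other group for 2979 genes, or 21.6%, against 10% by chance, and this held for all 730. The median log2 difference over all genes was -0.01. Arrays of the same group correlated at 0.991 to 0.998 across genes and arrays of different groups at 0.983 to 0.991, where genes are not independent replicates. The first principal component held 56.7% of the variance and separated the groups. The second held 24.0% and ordered the arrays by replicate number in both groups, for which the labels give no reason. Leaving out 1 array gave between 407 genes, without control replicate 2, and 1214, without laminin α1 replicate 3, with 429 without laminin α1 replicate 2.

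**Figure D1:**
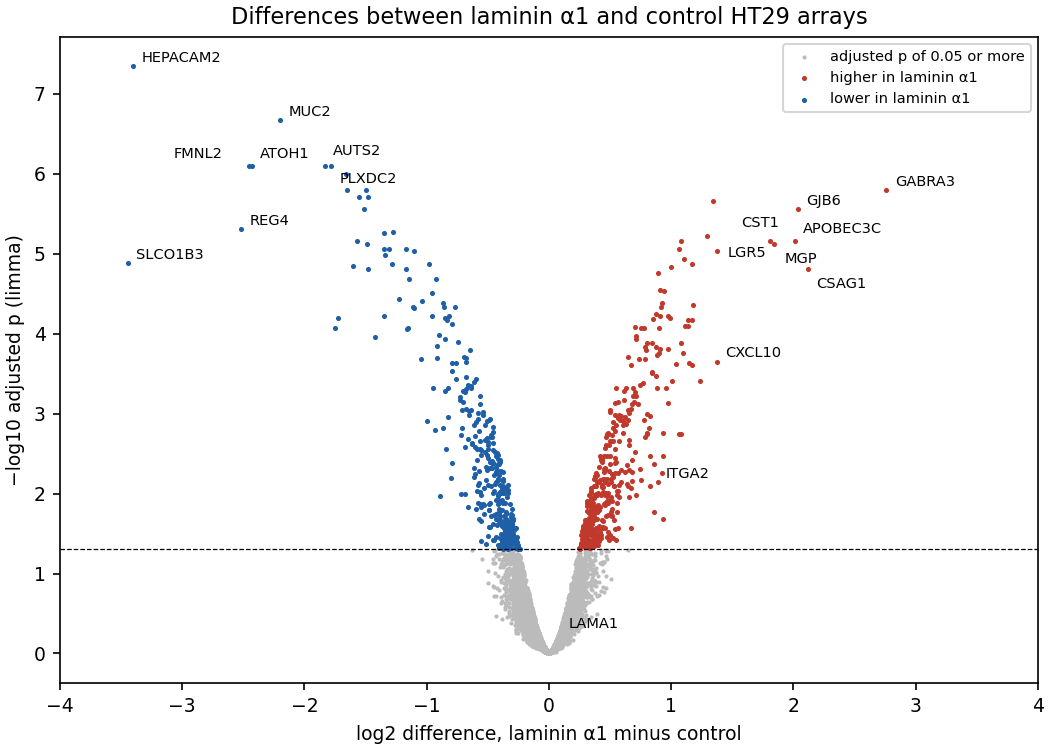
Each point is 1 of the 13812 genes, with the log2 difference (laminin α1 minus control) on the x axis and -log10 of the limma adjusted p on the y axis; red and blue points are the 372 higher and 358 lower genes past the dashed line at 0.05. HEPACAM2 and SLCO1B3 lie farthest to the left, GABRA3 farthest to the right, and LAMA1 below the line.

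Among the genes that rose most was GABRA3, a subunit of the GABA receptor, which went from 4.91 ± 0.22 to 7.68 ± 0.20 (SD, n = 3), a log2 difference of 2.76 (SE 0.12) or 6.78-fold, with adjusted p = 1.59e-06. CSAG1, a cancer-testis antigen, rose 4.34-fold and APOBEC3C, a cytidine deaminase active against retroviruses, rose 4.04-fold. Both have close family copies whose RNA could reach the same probes, so their values are uncertain. GJB6, a connexin of gap junctions, rose 4.10-fold and lay in a run of neighbouring genes that were higher together, 1 of 18 such runs found. MGP, an inhibitor of calcification in the matrix, rose 3.59-fold and CST1, a cysteine protease inhibitor, rose 3.51-fold. The control means of GABRA3, MGP and CST1 lay below the level filter of 5.50, where signal is low, so these folds are uncertain. With that level as the floor, the rises were at least 4.53-fold, 2.78-fold and 2.80-fold. CXCL10, a chemokine induced by interferon, rose from 7.55 ± 0.30 to 8.93 ± 0.15 (SD, n = 3), and LGR5 from 8.55 ± 0.04 to 9.92 ± 0.16.

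Among the genes that fell most were SLCO1B3, an organic anion transporter, from 8.28 ± 0.43 to 4.83 ± 0.40 (SD, n = 3), or 10.9-fold, and HEPACAM2, an immunoglobulin-family adhesion protein, from 8.85 ± 0.11 to 5.45 ± 0.12, or 10.6-fold. HEPACAM2 had the smallest adjusted p of all genes tested, 4.49e-08. REG4, a lectin secreted by goblet and enteroendocrine cells, fell 5.72-fold with a log2 difference of -2.52 (SE 0.14). FMNL2, a formin that builds actin filaments, fell 5.48-fold. AUTS2, a transcriptional regulator, fell 3.57-fold and PLXDC2, a membrane protein of the plexin domain family, fell 3.44-fold. The laminin α1 means of SLCO1B3, HEPACAM2, FMNL2 and AUTS2 lay below the level filter, so these folds are uncertain. With that level as the floor, the falls were at least 6.88-fold, 10.3-fold, 4.66-fold and 2.99-fold. HEPACAM2 and ATOH1 each lay in a run of neighbouring genes that were lower together.

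The secretory lineage list fell, with 12 of 25 tested members lower, 0 higher and 13 not past the threshold. The count adjusted over the list alone was also 12. MUC2 went from 8.80 ± 0.01 to 6.59 ± 0.10 and ATOH1 from 9.56 ± 0.17 to 7.13 ± 0.12 (SD, n = 3), and SPINK4, a goblet cell peptide, fell 2.81-fold. The mean log2 difference of the list was -0.65 and the median -0.17, since the members that did not pass lay near 0. The camera adjusted p was 3.98e-13, and the call was lost at adjusted p = 0.173 with an estimated correlation.

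Enterocyte differentiation genes fell as a list, with 5 of 22 lower and 0 higher, and 5 lower adjusted over the list alone. CEACAM6 fell 2.68-fold, DPP4, a peptidase of the brush border, 2.25-fold, CEACAM5 2.24-fold and KRT20 1.28-fold. CEACAM5 and CEACAM6 are adhesion molecules of the carcinoembryonic antigen family with similar sequences, and their values are uncertain for that reason. The list's mean was -0.21 and its median -0.02, with a camera adjusted p of 0.0198, and adjusted p = 0.583 with an estimated correlation. Without control replicate 1 the adjusted p was 0.117, in a range of 0.00257 to 0.117 over the arrays left out in turn.

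**Figure D2:**
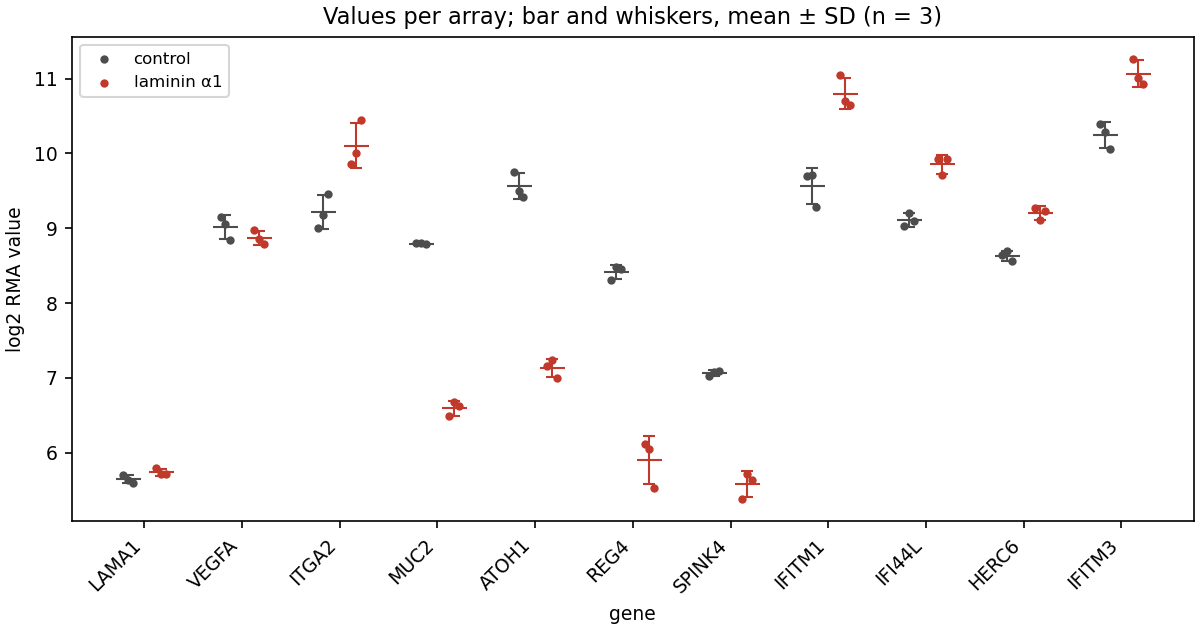
Points are log2 RMA values of single arrays for LAMA1, VEGFA, ITGA2, 4 secretory lineage genes and 4 interferon response genes; horizontal bars and whiskers are the mean ± SD of 3 arrays labelled control (grey) or laminin α1 (red). The groups overlap for VEGFA, the secretory genes are lower and the interferon genes higher in all 3 laminin α1 arrays, and LAMA1 differs by 0.09.

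Interferon response genes rose, with 22 of 34 higher and 32 of 34 adjusted over the list alone, and all 34 differences were positive. IFITM1 and IFITM3, membrane proteins that block virus entry, rose 2.36-fold and 1.77-fold, and IFI44L and HERC6 rose 1.68-fold and 1.49-fold. IFITM1 went from 9.56 ± 0.24 to 10.8 ± 0.21 (SD, n = 3). IFITM1 and IFITM3 are close in sequence, which makes the share of each uncertain. The mean log2 difference of the list was 0.53 and the camera adjusted p 4.31e-28, and the call was lost at adjusted p = 0.185 with an estimated correlation. The list's mean per array, against the control mean, was 0.03, 0.04 and -0.07 in the control arrays and 0.69, 0.43 and 0.46 in the laminin α1 arrays.

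Chemokines and their receptors had 2 of 9 tested members higher and 0 lower, with 2 higher and 1 lower adjusted over the list alone. The 2 were CXCL10 and CCL5, which attracts T cells and rose 1.42-fold. The list had a camera adjusted p of 0.0718 and was not called, although it was without control replicate 2 (adjusted p = 0.0401) and without control replicate 3 (adjusted p = 0.0269), in a range up to 0.128 over the arrays left out in turn. It was also called with the filter at the 50th percentile (adjusted p = 0.0463) and by fry (adjusted p = 0.00163), and not with an estimated correlation (adjusted p = 0.428). CXCR4, the receptor of CXCL12, was below the level filter, with 5.53 ± 0.06 in control and 5.02 ± 0.17 in laminin α1 arrays (SD, n = 3). In the limma fit without the filter the difference was -0.52 (SE 0.09, adjusted p = 0.00813), and its size is uncertain, since both means lay near or below the level filter of 5.50.

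Angiogenic factors rose as a list, with 5 of 22 higher and 0 lower, and 8 higher adjusted over the list alone. CXCL8, a chemokine that attracts neutrophils, rose 1.97-fold, EFNB2, a membrane ligand of Eph receptors, rose by log2 0.59, EDN1, the precursor of the vasoconstrictor endothelin, by log2 0.48 and PDGFC, a platelet-derived growth factor, by log2 0.40. VEGFA, the main endothelial growth factor, did not pass, at 9.02 ± 0.16 and 8.87 ± 0.09 (SD, n = 3), with a difference of -0.14 (95% interval -0.34 to 0.05, adjusted p = 0.479). EFNB2 and VEGFA each lay in a run of neighbouring genes that were higher together. The list's mean was 0.16 with a camera adjusted p of 0.00107, and adjusted p = 0.185 with an estimated correlation.

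NF-kB and inflammatory genes rose as a list, with 4 of 21 higher and 1 lower, and 6 higher and 1 lower adjusted over the list alone. PTGS2, the inducible cyclooxygenase, rose 2.05-fold, TNFAIP2 1.57-fold and LCN2, an iron-binding lipocalin, 1.24-fold. IL18, an inflammatory cytokine, fell 1.43-fold against the direction of the list. The mean was 0.14 and the camera adjusted p 0.00560, with adjusted p = 0.583 with an estimated correlation and 0.105 by fry.

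The laminin chain genes had 0 of 7 past the threshold, and 3 higher and 1 lower adjusted over the list alone. LAMB1 had a difference of -0.26 (SE 0.07, adjusted p = 0.0715), LAMB2 0.24, LAMB3 0.25 and LAMC1 0.17. LAMB1, LAMB2 and LAMB3 passed with array weights (adjusted p = 0.00181, 0.00229 and 0.00771), and LAMB2 and LAMB3 also without laminin α1 replicate 3 (adjusted p = 0.0456 and 0.0347). Integrins and laminin receptors had 4 of 20 higher and 0 lower, and the same counts adjusted over the list alone, with a camera adjusted p of 0.142, a fry adjusted p of 0.0448 and a median of 0.0062. ITGA2 went from 9.22 ± 0.23 to 10.1 ± 0.30 (SD, n = 3; adjusted p = 0.00722), while BCAM, a receptor of laminin α5, rose 1.57-fold, ITGA9 1.43-fold and ITGB7 1.25-fold. ITGA2 lay in a run of genes that were higher together and BCAM in a run that was lower, and with all 33297 probe sets tested separately the adjusted p of ITGA2 was 0.0524, the highest of its alternatives. ITGB1, the partner of ITGA2, had a difference of -0.20 (95% interval -0.43 to 0.02, adjusted p = 0.360).

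Other basement membrane and matrix genes had 1 of 18 higher and 2 lower, and 2 higher and 2 lower adjusted over the list alone, with a camera adjusted p of 0.574. NTN4, a laminin-related netrin, and HSPG2, the proteoglycan perlecan, fell 1.34-fold and 1.29-fold, and FREM2, which lay in a run of higher genes, rose by log2 0.49. Focal adhesion and actin genes had 3 of 26 higher and 2 lower by either adjustment (over all genes or adjusted over the list alone), with a camera adjusted p of 0.559. CNN3, an actin-binding calponin, rose 1.84-fold, and TPM1, a tropomyosin, fell 1.52-fold. Proteases and inhibitors had 3 of 23 higher and 1 lower by either adjustment, at a camera adjusted p of 0.553. MMP7, a matrix metalloproteinase that lay in a run of lower genes, fell 2.42-fold, while its mean of -0.0049 and the upward direction of camera made the list's signs differ.

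Wnt target genes moved both ways, with 2 of 21 higher and 4 lower, and 3 higher and 4 lower adjusted over the list alone. LGR5 rose, while DKK1, a secreted Wnt inhibitor, fell 2.54-fold, EPHB3, an Eph receptor of the crypt, 1.83-fold and KIAA1549 1.39-fold, with a camera adjusted p of 0.517 for the list. Colon stem cell and progenitor markers had 1 of 15 higher, LGR5 again, and 1 lower, PROM1, a membrane glycoprotein that fell 1.80-fold. Adjusted over the list alone these were 4 and 1, and camera gave adjusted p = 0.193 and fry 0.0350. Epithelial junction and keratin genes had 1 of 27 higher and 4 lower, and 1 and 6 adjusted over the list alone, with a camera adjusted p of 0.336 and a fry adjusted p of 0.0454. CDH17, the cadherin of intestinal epithelium, fell to a mean below the level filter, at least 2.12-fold with that level as the floor, and the tight junction gene CLDN1 fell 1.68-fold while CLDN2 rose 1.60-fold. The mean of that list was -0.11, with the downward direction of camera, and the median 0.04.

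Mesenchymal transition genes had 0 of 18 higher and 1 lower by either adjustment, CCN2, a matricellular growth factor that fell 1.58-fold. Camera pointed upward (adjusted p = 0.904) although the mean was -0.03. Growth factor signalling and immediate early genes had 3 of 27 higher and 1 lower, and 4 and 4 adjusted over the list alone (camera adjusted p = 0.696). IER3, an early response gene in a run of higher genes, rose 1.79-fold, and EREG, a ligand of the EGF receptor, fell 1.73-fold. The list's mean of 0.01 and median of -0.04 differed in sign. Hypoxia and glycolysis genes had 2 of 27 higher and 2 lower, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.517), with P4HA2, a collagen prolyl hydroxylase, 1.36-fold higher and NDRG1 1.33-fold lower. NRF2 and xenobiotic metabolism genes had 1 of 21 higher, HMOX1, and 1 lower, AKR1B10, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.840).

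Proliferation genes of the cell cycle list had 1 of 39 higher and 0 lower by either adjustment (camera adjusted p = 0.626), the 1 being CCNB1, a mitotic cyclin in a run of higher genes that rose 1.38-fold. The mean of the list was 0.0084 and the median -0.02. Of the p53 target genes 1 of 19 was lower by either adjustment, TP53INP1, which fell 1.43-fold (camera adjusted p = 0.193, fry adjusted p = 0.0454). None of 26 unfolded protein response genes (camera adjusted p = 0.193) and none of 22 cholesterol and lipid synthesis genes (adjusted p = 0.904) passed by either adjustment. The mean of the cholesterol list was -0.02 and its median 0.01. Markers of other cell types showed 0 of 7 fibroblast genes past the threshold by either adjustment (camera adjusted p = 0.751) and 1 of 9 endothelial and blood cell genes, LYN, a kinase that fell 2.06-fold, also by either adjustment (camera adjusted p = 0.740). Among 13 housekeeping genes 1 was higher by either adjustment, SDHA by 1.24-fold, with a camera adjusted p of 0.751, a mean of -0.0025, a median of 0.02 and an upward direction of camera.

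**Figure D3:**
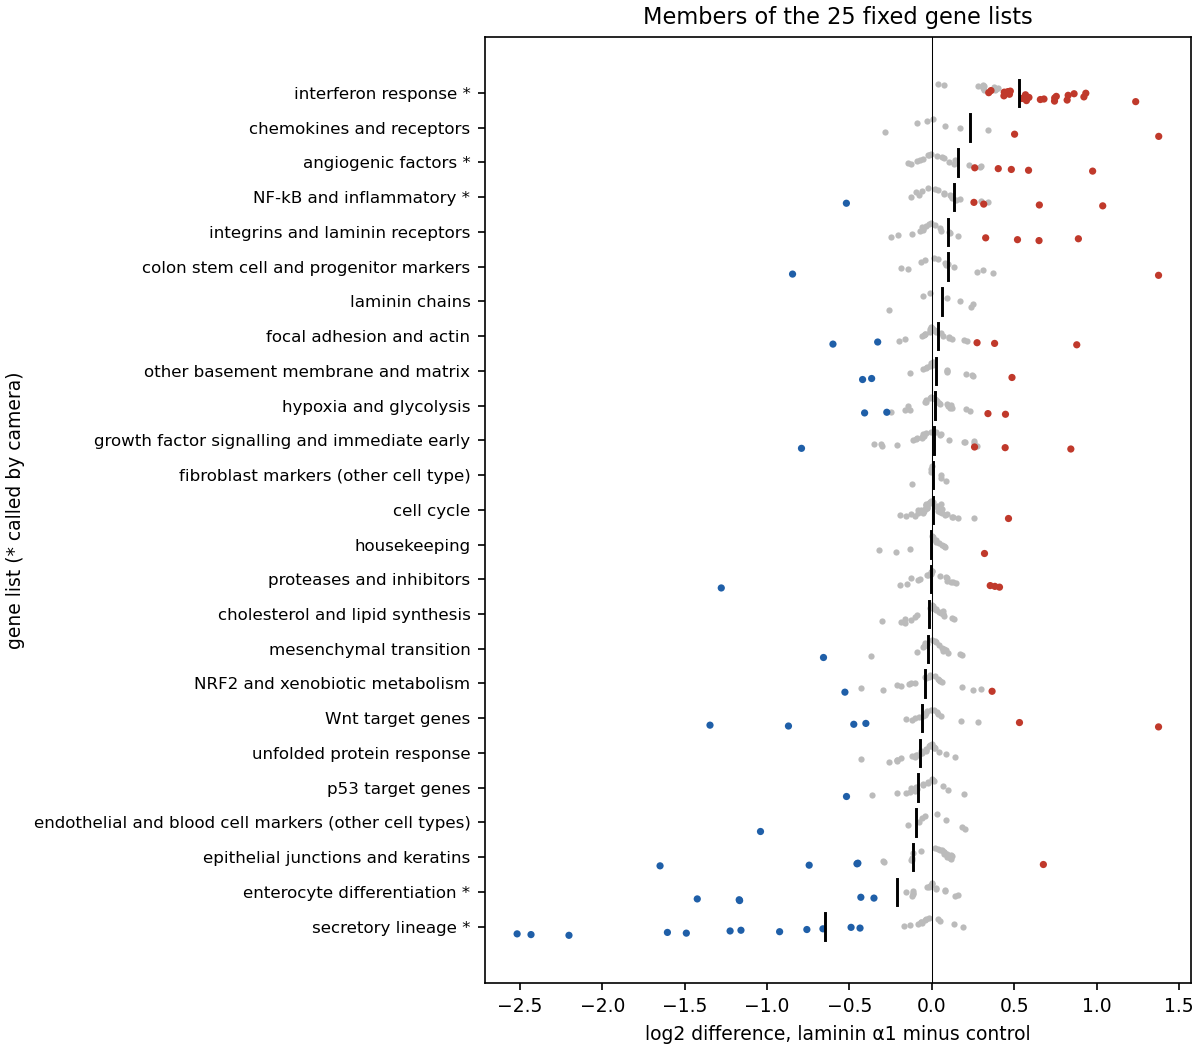
Each point is the log2 difference (laminin α1 minus control, x axis) of 1 tested member of the 25 gene lists on the y axis; red and blue points passed the limma threshold, black bars are list means, and asterisks mark the 5 lists called by camera. The interferon response list has the highest mean, 0.53, and the secretory lineage list the lowest, -0.65.

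Of the 25 lists, 5 were called by camera, 3 upward and 2 downward, and 0 were called with an estimated correlation, where the smallest adjusted p was 0.173. Fry called 9, the chemokine, integrin, stem cell, junction and p53 lists among them without a call by camera, and did not call the NF-kB list. The calls of EGLN3 in the hypoxia list and PHLDA1 in the growth factor list were lost whichever of the 6 arrays was left out. Those of HSPG2, FREM2, ITGB7, TNS1, TNS4, PDGFC, KRT20, ADAM8, TIMP2, LCN2, IL18, NDRG1, DUSP4, AKR1B10, HMOX1 and SDHA were lost without at least 1 of the arrays.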

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

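The tests of other splits of the arrays in this part were chosen after the results had been seen. Signal differed between the groups in probe sets that the comparison of named genes does not use. In a limma fit over all 33297 probe sets, 101 probe sets that the annotation does not list passed the threshold, 65 higher and 36 lower in the arrays labelled laminin α1. Probe set 8140504 went from 6.38 to 8.17, a log2 difference of 1.79 (SE 0.06, adjusted p = 4.36e-05), and probe set 7954344 had a difference of -1.66. A further 39 probe sets that the annotation ties to several genes passed, 18 higher and 21 lower. Probe set 8175747 had a difference of 2.14 and probe set 8094134 one of -1.48. No gene is named for these probe sets.

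The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 730 genes past the threshold and the highest of the others 0, so 1 of 10 splits gave as many. The other splits mix arrays of both groups, so a real group difference adds to the spread within their parts. Genes that differ between the groups are thereby kept from passing, and the count of 0 is not a chance baseline. For lists called by camera the real split gave 5 and the highest of the others 3, again 1 of 10. Most of the other splits had at least 1 list called, though 0 genes passed in them. A call by camera at the preset correlation therefore does not by itself mark a difference between the groups. At an unadjusted p under 0.05 the real split gave 2310 genes. The split that put control replicate 1 with laminin α1 replicates 1 and 2 gave 2297, a structure of the arrays that does not follow the groups.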

How the results depend on the processing

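The removal of the genes in shifted runs was the only alternative chosen after seeing the data. Over the alternatives, 79 named genes other than LAMA1 gave 1153 values: 1061 kept direction and side of the threshold, 84 lost the threshold, 8 gained it (all of them LAMB1, LAMB2 or LAMB3) and 0 reversed. The LAMA1 adjusted p lay between 0.239 and 0.806. Against 730 genes (372 higher, 358 lower), array weights gave 2607 (1208 and 1399), an adjusted p under 0.01 gave 393 (200 and 193) and a fold of at least 2 gave 67 (28 and 39), the last 2 by their construction. Without the run genes 526 passed, 238 of them higher. With the replicate number as a block 1596 passed (746 and 850), the 730 included, LAMB1, LAMB2 and LAMB3 passed (adjusted p = 0.0257, 0.0372 and 0.0312), and the enterocyte list was lost (adjusted p = 0.0644, in a range of 0.00505 to 0.583 over all but the left-out arrays). The numbers were not taken as pairs: deviations of arrays with the same number correlated at 0.39, 0.02 and 0.53. Control replicates 1 and 3 correlated best with their own number and control replicate 2 with laminin α1 replicate 1, a hint from the data, not the design. Leaving out each array gave 407 to 1214 genes, 208 to 532 higher and 192 to 682 lower. The extremes came without control replicate 2 (407), laminin α1 replicate 2 (429) and laminin α1 replicate 3 (1214), and 238 were lower without control replicate 1. Lists called numbered 5, against 0 with an estimated correlation, 9 with fry and 4 to 6 with an array left out. Within-group minus between-group correlation was 0.0059, and 0.0028 with no filter or 0.0095 with the stricter one. Reversed lists were all uncalled, with means near 0. Proteases turned to 0.011 with no filter, 0.0033 with quantile normalization, 0.0010 with array weights and 0.059 without run genes. Hypoxia turned to -0.0057 with the stricter filter and cell cycle to -0.00056 with array weights. Without run genes cell cycle was -0.0026, basement membrane -0.0038 and growth factor signalling -0.026. With an array left out, means ranged from -0.0014 to 0.067 for focal adhesion, -0.018 to 0.0077 for proteases, -0.013 to 0.030 for cell cycle, -0.0023 to 0.043 for hypoxia, -0.019 to 0.042 for growth factor signalling, -0.019 to 0.049 for fibroblast markers and -0.017 to 0.0087 for housekeeping. Apart from those construction effects the cause was not tested. Low signal limits LAMA1, CXCR4 and genes with 1 group below the level filter, such as SLCO1B3 and GABRA3.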

Other observations

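All tests of explanations in this part were chosen after the results had been seen. Members of several gene families changed. The families were chosen after their values were seen, and their enrichment was not tested. Of 5 tested APOBEC3 genes, cytidine deaminases that act against retroviruses, 4 rose, with log2 differences of 2.01 for APOBEC3C, 1.18 for APOBEC3F, 1.01 for APOBEC3G and 0.53 for APOBEC3B. APOBEC3D had 0.20 and did not pass. The members are similar in sequence, so how the signal divides among them is uncertain. The 3 vault RNA genes rose, VTRNA1-2 by 2.26-fold, VTRNA1-3 by 1.91-fold and VTRNA1-1 by 1.60-fold. Whether their probe sets share signal was not examined, so these need not be separate rises.

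PTGS1, the constitutive cyclooxygenase, rose 2.20-fold beside the 2.05-fold rise of PTGS2. Of 11 connexin genes 3 rose, GJB6, GJA5 by 2.20-fold and GJB2 by 1.88-fold, and 8 did not pass. Falls were seen for 3 of 4 STEAP metalloreductase genes, STEAP1 by 1.86-fold, STEAP2 by 1.65-fold and STEAP4 by 1.35-fold, while STEAP3 had a difference of 0.24 and did not pass. Falls were also seen for 2 of 4 alcohol dehydrogenase genes, ADH1C and ADH6, both with a log2 difference of -1.35, and the other 2 did not pass. Whether the STEAP and alcohol dehydrogenase genes, GJB2 and GJA5 lie in the runs of neighbouring genes was not looked up. A change of the family therefore cannot be told apart from a shift shared with neighbouring genes.

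Neighbouring genes shifted together in 18 runs, 8 higher and 10 lower. They held 965 genes (6.99%) and 177 of the 730 genes past the threshold (24.2%). The runs were sought on the same log2 differences that the threshold tests, so the larger second share is partly built in. The strongest were TENT4A to TNPO1, with 123 genes, a median log2 difference of 0.22 and 29 genes past the threshold, and BAGE5 to ATP7B, with 133 genes, a median of 0.22 and 53 past it. GJB6 lies in BAGE5 to ATP7B, ITGA2 in TENT4A to TNPO1, HEPACAM2 in the lower run ADAM22 to DLX6 and ATOH1 in the lower run FAM13A to BDH2.

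A second search, on every other gene, found 6 runs, and the 153 genes left out within them served as a check. A brightness bias of the arrays is argued against as the source of these 6 runs. Of 1000 random lists matched on level, 0 reached the shift of the left-out genes. The check does not cover runs that the second search did not find. The group difference exceeded the range of the 3 arrays within a group in 9 of the 18 runs, by the most in BAGE5 to ATP7B at 2.38 times, and not in the others. With 3 arrays per group and runs found by their group difference, a gradient between arrays that both groups share cannot be told apart from a group difference. In the search on every other gene, 80.4% of the 153 genes left out shifted the way of their run. A regional difference between the cell populations, of DNA copy number or of regulation, may be the source. The left-out genes were measured on the same 6 arrays, so an array effect shared by neighbouring genes could give the same result.

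A single array is argued against as the source of the rise of the interferon list. The list's mean stayed at 0.45 or more with each array left out. Of its 34 tested members 3 lay in the runs. The mean without these 3 was 0.52, so the rise was not confined to them. With so few members removed, the mean could barely move, so this does not decide whether the runs contributed. The labels name only cultured HT29 cells, an established cell line, and give no source of fibroblast, endothelial or blood cell RNA. The markers of those cells alone cannot exclude a small share of such RNA, since it would be hidden by their baseline signal. The 36 markers on the array had a mean difference of -0.017 (SE 0.033) in the limma fit without the filter, or 0.012 without LYN, which fell by 1.04, and 0 of them were higher past the threshold. The most abundant others, ENG, CD68 and COL1A1, at mean levels of 8.19, 7.75 and 7.37, had differences of 0.18, 0.09 and 0.06. The construct itself, its delivery and other differences between the cell populations behind the groups stay open as untested explanations, since each group carries 1 construct.

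The fall of the secretory list is argued not to come from a single array, since its mean stayed at -0.63 or lower with each array left out. Of its 25 tested members 2 lay in the runs, ATOH1 and SPDEF. ATOH1 fell, while SPDEF had a log2 difference of -0.07 and did not pass (limma adjusted p = 0.732). The mean without these 2 was -0.59, so the fall was not confined to them. With so few members removed, this does not decide whether the runs are a source. An effect of ATOH1 on members outside the runs was not tested. The construct and other differences between the cell populations stay open as untested explanations here too.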
